A study of Arabidopsis thaliana with 16 samples.

How the data were processed

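Peak lists from 8 anti-WRKY immunoprecipitations of Arabidopsis seedlings were used, 2 biological replicates in each of 4 groups (WT and the wrky18 wrky40 wrky33 triple mutant, at 0 h and 2 h of 1 µM flg22). Per the labels' protocols, precipitated DNA went through linear amplification ahead of library construction, and single-end reads were sequenced. Per the labels, the 8 input libraries were negative controls for peak calling, and their data were not used here. The submitters' processing notes name FastQC 0.11.2, cutadapt 1.2.1, Bowtie2 2.0.5, SAMtools 0.1.18, HOMER and the build TAIR10. The peak caller and its settings are not given in the sources used here. Amplification can change the balance between fragments, and shared settings and thresholds decide which sites enter a list at all.

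The deposited tables hold 1 list per library, so replicates can be compared as calls. Each row gives a region number, start, end, position of the maximum, 3 scores (a ChIP score, an ef score and a region log q score), an annotation class, the distance to the TSS and the nearest promoter's gene. The authors' peak score is that peak's own value within its list, and its scale is not given in the sources used here. It was used only to rank, describe and filter peaks within a list, as a percentile (100 for the top peak). The lowest ChIP score was about 10 in every list (9.98 to 10.0), and the lowest ef score was between 2.51 and 2.90. All peaks lay on chromosomes 1 to 5. The table for WT 0 h replicate 1 ran to region number 1508 but held 1372 peaks, so 136 numbers (9.02%) were absent, spread over the list from number 4 on; the other 7 tables had no gaps. Region numbers in that table followed the score order (Spearman rho 0.9999), so by their numbers the absent peaks were not only weak ones.

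Peaks of all lists were merged where they shared at least 1 bp, which gave 3886 regions with a median width of 493 bp. Chains of wide peaks can join neighbouring sites, and cutting peaks to 150 bp was one of the alternatives. A region was gained or lost when called in both libraries of one group and neither of the other. The design was fixed before the data were examined, as were the gene lists and the rule for naming genes: per comparison and direction, the 12 list genes and the 5 other genes with the highest mean score percentile, with WRKY18, WRKY40, WRKY33 and FRK1 always, and the 5 highest members of each list past its test. Of 86 differences named by this rule, 10 had no region that met it, and this comparison was made after seeing the data. Those with a site called in both libraries of the other group were left out of the text, since the nearest gene can change between libraries at one site. One gene that this rule would name is not reported here. With 2 libraries against 2 the smallest exact two-sided p is 0.333, so each count stands beside the 2 other splits of the same 4 libraries. Contrasts of 4 against 4 libraries were set beside the 35 possible splits.

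Genes were taken from the authors' nearest-promoter assignment, at any distance. Of 3609 assigned genes, 3564 were found in the RefSeq gene table of the TAIR10.1 assembly, which was used for names and for the background of 27444 nuclear protein-coding genes; no coordinates were taken from it. All 338 genes of the 12 fixed lists were found there. Lists were tested with Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 48 tests of bound genes (a peak in both libraries of a group) and over 96 tests of gained or lost genes, for which the background was genes with a peak in at least 1 of the 4 libraries. Per-library values were compared by exact permutation tests, two-sided. The threshold was an adjusted p of 0.05.

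The series' design text states that 4 conditions were analysed for each of 2 biological replicates, so the replicate number marks a shared replicate. The differences in calls between replicates 1 and 2 correlated between groups across regions (0.320 to 0.459), and lists of the same number shared more regions (43.8% to 64.2% of the union of a pair) than lists of the same group (37.4% to 43.1%). Median region width was 525 to 564 bp in replicate 1 and 354 to 385 bp in replicate 2. The gain and loss rule already asks for the change in both pairs. The paired alternative was the mean count within same-numbered pairs.

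Alternatives fixed beforehand were only the peaks above each list's median score, equal numbers of peaks (the top 1372), peaks cut to 150 bp, a relaxed rule, leaving out each library, genes in place of regions, TSS windows for gene assignment (2000 or 1000 bp upstream to 500 bp downstream) and another background. Those chosen after seeing the data were a background of all 37899 nuclear genes for bound lists counting WT 0 h replicate 1 at its highest region number, alone and with the replicate block, and paired and leave-one-out tests of gene number, promoter share and intergenic share. On simulated lists modelled on WT with and without flg22 (3886 regions), 177 of 200 seeded gains (88.5%) were recovered. Another 104 regions without a seeded gain also met the rule. The call rates set for seeded gains decide the recovered share, so it does not show how often real gains are found. In the real WT lists the split by replicate number gave 281 and 193 regions, against 9 and 22 across time and replicate. Calls were thus tied by replicate number, and the 104 cannot serve as an error rate for the 254 regions gained in WT. On simulated gene lists over 27444 genes, 200 of 200 enriched lists were recovered and 2 of 200 random lists passed, at an unadjusted p below 0.05. Every enriched list held the same number of members and of bound genes, so their recovery was fixed by the setting. It does not show how often the shorter real lists would pass after adjustment. A search for W-box sequences and a test of tag counts had been planned and were not run, since no genome sequence or tag counts were used here. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.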

Results

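Chromatin of 12-day-old Arabidopsis thaliana seedlings was immunoprecipitated with a serum raised against all WRKY proteins, the plant transcription factors that bind the W-box element. Plants were wild type (WT, accession Col-0) or a triple mutant of WRKY18, WRKY40 and WRKY33, and were taken untreated (0 h) or 2 h after 1 µM flg22, a bacterial flagellin peptide that triggers immune signalling. No group was taken at 2 h without flg22, so an effect of flg22 cannot be told apart from elapsed time or handling. Each of the 4 groups had 2 biological replicates, which gave 8 immunoprecipitated libraries, each with its own peak list. Another 8 libraries of input DNA served as controls for peak calling and had no peak list here. Read and tag counts per library were not analysed here, so the depth behind a single call is unknown. The lists held 14333 peaks, which merged into 3886 regions. Of these regions, 496 were called in all 8 libraries and 1023 in 1 library.

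Of the 496 regions called in every library, the highest mean score percentile over the 8 lists was 99.4, at CAD1 (AT5G44070, a phytochelatin synthase), on chromosome 5 at 17733816 to 17734950 (TAIR10) and -308 bp from the transcription start site (TSS). Next came PROPEP3 (AT5G64905), the precursor of a damage-signalling peptide, with 98.9 at a promoter region on chromosome 5 at 25938768 to 25940113, and AT2G43620 with 98.7. ERF1A (AT4G17500), an ethylene response factor, had 98.6 at an intergenic region on chromosome 4 at 9757126 to 9757622. They were followed by AT1G12190 (98.1), ACLA-1 (97.9), AAT1 (97.4), AT5G46295 (97.2), AT1G59910 (97.1) and AT5G43420 (97.0). Whether these regions share a function was not tested.

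The first question was how many sites were occupied at 0 h and at 2 h after flg22. The lists held 1372 and 1466 peaks in WT at 0 h and 1992 and 2074 in WT at 2 h. In the triple mutant they held 1447 and 1720 peaks at 0 h and 2049 and 2213 at 2 h. Over both genotypes this was 2082 ± 93.8 peaks at 2 h (SD, n = 4) against 1501 ± 151 at 0 h (SD, n = 4), and the number of assigned genes was 1933 ± 95.3 against 1447 ± 136. Both differences had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries can give. The mutant lists held 1857 ± 342 peaks against 1726 ± 358 in WT (SD, n = 4 each; exact permutation p = 0.6). For peaks per library, wrky18/40/33 minus WT, signs permuted within pairs gave an exact p of 0.125, the smallest possible. This paired p was 0.375 with WT 0 h replicate 1, whose table lacked 136 peaks by its numbering, counted at its highest number of 1508. For peaks per library, 2 h minus 0 h, the difference was 580.8, and with signs permuted within same-numbered pairs the exact p was 0.125, the smallest possible. With peaks of ef score 5 or more the difference was 439 (exact permutation p = 0.143, unpaired). Such peaks rose from 1106 to 1361 and from 1406 to 1986 in replicates 1 and 2 of WT. In the mutant they rose from 1131 to 1449 and from 1524 to 2127, so the unpaired test also holds the spread between replicates. Of the 2 h peaks 62.8% ± 1.77 were annotated as promoter, against 67.0% ± 0.313 at 0 h (SD, n = 4 each; exact permutation p = 0.0286). The intergenic share was 16.8% ± 1.76 at 2 h and 13.8% ± 0.429 at 0 h (exact permutation p = 0.0571). Within pairs, the exact p for genes, promoter share and intergenic share was also 0.125.

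**Figure D1:**
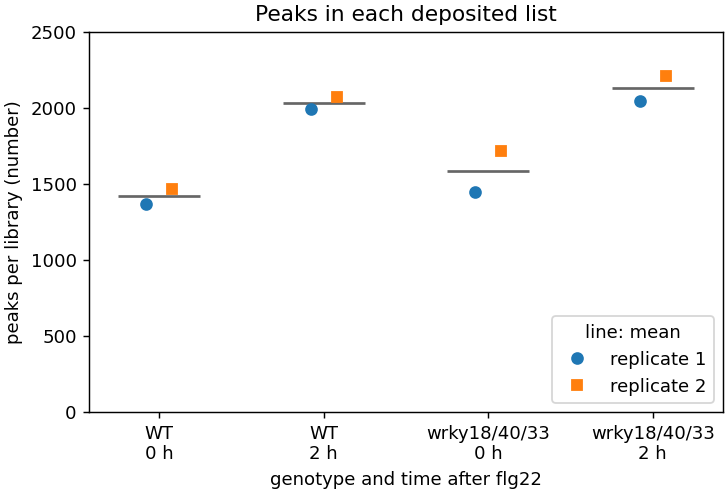
Peaks in each of the 8 deposited lists (vertical axis, number) by genotype and time after flg22 (horizontal axis); circles are replicate 1, squares replicate 2 and lines group means. The 4 lists at 2 h hold 1992 to 2213 peaks and the 4 at 0 h hold 1372 to 1720.

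Which immune gene groups carried peaks was asked with 12 gene lists fixed before the data were examined. WRKY genes themselves were bound far more often than other genes: 11 of 72 had a peak in both libraries of WT at 0 h (15.3%, against 2.80% of other protein-coding genes), 17 of 72 in WT at 2 h (23.6% against 3.82%), 10 in the mutant at 0 h and 14 in the mutant at 2 h. Fisher's exact test, two-sided, gave adjusted p-values of 3.76e-05, 1.91e-08, 0.000333 and 4.89e-06 for these groups. There were 9 WRKY genes with a peak in all 8 libraries: WRKY8, WRKY15, WRKY17, WRKY30, WRKY40, WRKY41, WRKY48, WRKY53 and WRKY60. In WT at 2 h the strongest were WRKY53, with a score percentile of 98.1 ± 0.247 (SD, n = 2), WRKY33 with 93.7 ± 0.638 and WRKY15 with 92.2 ± 7.16. The strongest peak lay at -234 bp from the TSS for WRKY53, at -12 bp for WRKY30 and at -2759 bp for WRKY15.

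**Figure D2:**
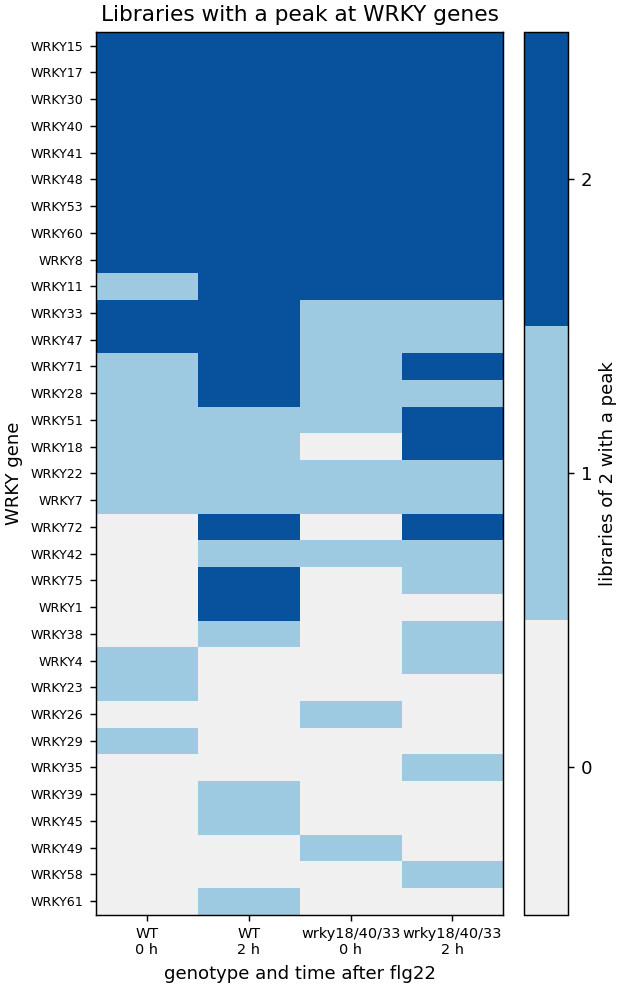
Number of libraries, of 2 per group, with a peak assigned to each WRKY gene (rows) in each genotype and time after flg22 (columns); the 33 WRKY genes with a peak in at least 1 library are drawn. The top 9 rows carry a peak in all 8 libraries.

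Genes of microbial pattern perception and early signalling were bound at 9 of 50 in WT at 0 h, 17 in WT at 2 h, 14 in the mutant at 0 h and 17 in the mutant at 2 h (34.0% against 3.82% of other genes in WT at 2 h; odds ratio 13.0, Fisher's exact adjusted p = 6.20e-11). PROPEP3 had a score percentile of 99.5 ± 0.507 in WT at 2 h (SD, n = 2). The chitin receptor kinase CERK1, at -109 bp from its TSS, had 94.7 ± 4.37, and LORE, a receptor kinase for bacterial lipid metabolites, had 89.3 ± 5.94. The MAP kinase kinase MKK2 and the immune ubiquitin ligase PUB23 were also called in all 8 libraries. Genes of camalexin and indole glucosinolate synthesis, the antimicrobial metabolites of this family, were bound at 6 of 31 in WT at 0 h, 8 in WT at 2 h, 5 in the mutant at 0 h and 9 in the mutant at 2 h, with Fisher's exact adjusted p-values from 1.30e-05 to 0.00601. PEN3, PEN2, IGMT2 and GSTF6 were called in all 8 libraries. The regulator MYB51 was called in both libraries of WT and of the mutant at 2 h and in 1 of 2 at 0 h in each.

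Ethylene pathway genes were bound at 4 of 21 in WT at 0 h, 7 in WT at 2 h, 3 in the mutant at 0 h and 4 in the mutant at 2 h (Fisher's exact adjusted p = 0.00601, 5.27e-05, 0.0465 and 0.0146). ERF1A, ACS6 and ACS8 were called in all 8 libraries, the last 2 encoding enzymes of ethylene synthesis. With peaks from 2000 or 1000 bp upstream to 500 bp downstream of the TSS the list passed in no group, at lower odds ratios, and with only peaks above each list's median score it passed in WT at 2 h alone, although the odds ratios did not fall. Among other stress-associated transcription factors, 3 or 4 of 11 were bound in each group (Fisher's exact adjusted p at most 0.0146), with ZAT10, ZAT11 and MYB15 called in all 8 libraries; with the 1000 bp window this list passed in WT at 2 h alone. Cysteine-rich and wall-associated kinases were bound at 3 of 21 in WT at 0 h (Fisher's exact adjusted p = 0.0366) and at 6 of 21 in each of the other groups (adjusted p at most 0.000376). CRK14 (98.8 ± 0.521 in WT at 2 h, SD, n = 2), CRK45 and CRK10 were called in all 8 libraries.

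VQ-motif proteins, partners of WRKY factors, passed the test in the mutant, at 3 of 8 at 0 h (Fisher's exact adjusted p = 0.00391) and 4 of 8 at 2 h (adjusted p = 0.000425), against 1 and 2 of 8 in WT (adjusted p = 0.286 and 0.0595). They also passed in WT at 2 h with either TSS window or with all nuclear genes as background, and the difference between genotypes was not tested. Jasmonate genes passed in WT at 2 h, with 4 of 21 (LOX3, LOX4, JAZ1 and JAZ6; Fisher's exact adjusted p = 0.0146), and intracellular immune receptors in the mutant at 0 h, with 5 of 22 (NRG1A, RPM1, ADR1-L1, NRG1B and ZAR1; adjusted p = 0.00146). With only peaks above each list's median score none of these VQ, jasmonate and receptor calls passed, and no VQ gene was bound in the mutant at 0 h (odds ratio 0). Salicylic acid genes did not pass in any group, with at most 3 of 30. Of the control lists, no housekeeping gene (of 14) was bound and photosynthesis genes reached 1 of 37 in WT at 0 h. Peaks were assigned to the nearest promoter at any distance, which favours genes beside long intergenic stretches, and genes are not independent replicates.

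**Figure D3:**
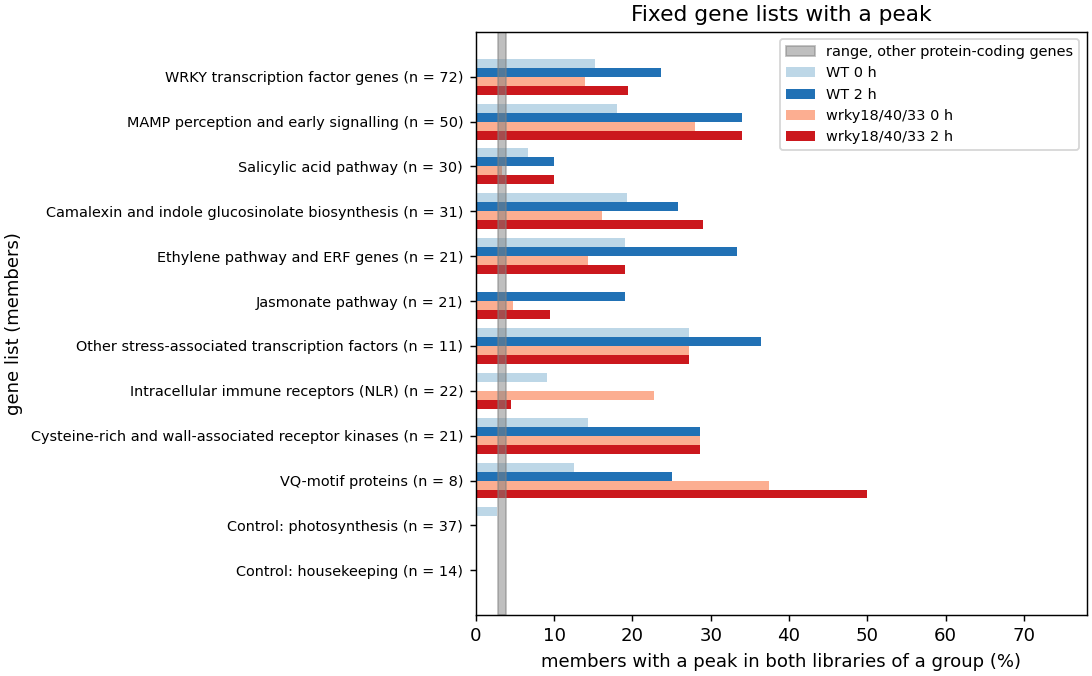
Share of each fixed gene list (vertical axis, with its number of members) that had a peak in both libraries of a group (horizontal axis, %), one bar per genotype and time; the grey band spans the 4 groups' shares of other protein-coding genes. Pattern perception genes reach 34.0% in WT at 2 h, and the housekeeping control list stays at 0.

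The effect of flg22 in WT was read as regions called in both libraries at 2 h and in neither at 0 h (gained), or the reverse (lost). In WT 254 regions were gained and 68 lost. The same rule applied to genes in place of regions, whichever of their sites was called, gave 235 gained and 65 lost genes, of which 215 and 63 had a gained or lost region. Members of the fixed lists accounted for 16 of the gained genes. The strongest were PUB24 (AT3G11840, a ubiquitin ligase that dampens immune signalling; chromosome 3, 3738211 to 3738557, at -127 bp from the TSS; percentile 76.1 ± 2.35, SD, n = 2), the ethylene synthesis gene ACS7 (65.5 ± 17.3), the indole glucosinolate methyltransferase IGMT1 (60.6 ± 14.1) and the immune regulator SAG101 (56.9 ± 20.0). They were followed by the receptor PEPR1, the jasmonate repressor JAZ6, ERF5, NAC055, the camalexin gene CYP71A12, CRK2, WRKY72 (38.3 ± 1.86) and WRKY75 (35.9 ± 47.1). The strongest peaks of ACS7, ERF5 and NAC055 lay near transcript ends, at 1372 to 2780 bp downstream of the TSS. Those of JAZ6, CYP71A12, WRKY72 and WRKY75 were intergenic, at -1189 to -2786 bp. CYP71A12 and WRKY72 were called at different sites in the 2 libraries, so neither had a region that met the rule. Outside the lists the highest were AT1G26380 (97.0 ± 3.76), BGLU27 (92.3 ± 4.098), HSF A4A (89.5 ± 6.17), AT2G02210 and AT3G48640. PEPR1, CRK2, AT1G26380 and HSF A4A were also called in both mutant libraries at 0 h. Of the 254 gained regions, 72 were called in at least 1 mutant library at 0 h and 182 in none. The list of WT 0 h replicate 1 lacked 136 region numbers, so an absent call at 0 h can also be an absent row.

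In WT 3 list genes were called in both libraries at 0 h and neither at 2 h: the immune receptor RPM1 (chromosome 3, 2229050 to 2229406; 56.6 ± 8.79, SD, n = 2), the MAP kinase MPK3 (47.0 ± 8.01) and the helper receptor NRG1A (12.4 ± 8.31). RPM1 and MPK3 were called in all 4 mutant libraries. LOX1 (72.7 ± 26.8), AT3G26440, AT3G25720 and ESK1 were among the highest of the other lost genes. No list was over-represented among gained or lost genes in any of the 4 comparisons (Fisher's exact test, 96 tests, of which 2 had an unadjusted p below 0.05). The closest was the intracellular immune receptors lost in the mutant, 2 of 10 (Fisher's exact adjusted p = 0.0781). Without WT 0 h replicate 1 these receptors passed among lost genes in WT (5 of 7, Fisher's exact adjusted p = 0.00801), and without replicate 1 of the mutant at 2 h among genes called in the mutant alone at 2 h (6 of 8, adjusted p = 0.0342). With 2 libraries against 2 no p below 0.333 is possible, and the same 4 libraries split across time and replicate gave 9 and 22 regions, while the split by replicate number gave 281 and 193. Cut to the 1372 top peaks of each library, the lists gave 105 gained and 125 lost regions (45.7% gained against 78.9% as deposited). Equal lengths push gains and losses towards balance whether or not flg22 adds sites, so this cannot test the excess. Within replicate pairs 1 and 2 alone 961 and 883 regions were gained and 347 and 316 lost.

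**Figure D4:**
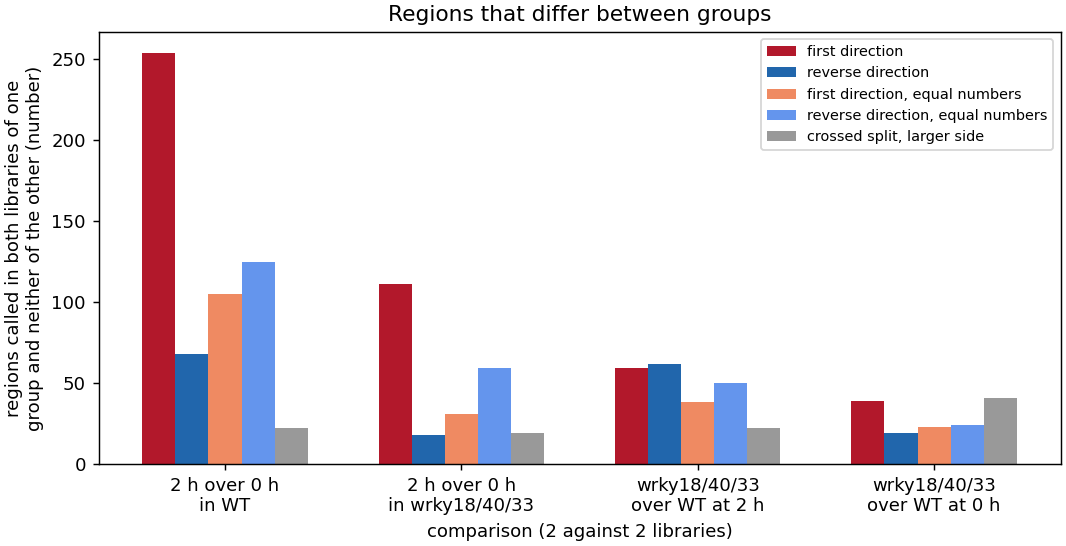
Regions called in both libraries of one group and neither of the other (vertical axis, number) in the 4 comparisons of 2 against 2 libraries (horizontal axis); dark bars use the lists as deposited, pale bars equal numbers of peaks per library, and grey bars the larger side of the split across group and replicate. In WT 254 gained regions stand against 68 lost, and 105 against 125 with equal numbers.

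In the triple mutant 111 regions were gained after flg22 and 18 lost. Counted by gene the numbers were 111 and 17, of which 97 and 16 had a gained or lost region. Of the list genes, 6 were gained: PUB24 (56.3 ± 25.8, SD, n = 2), WRKY72 (51.2 ± 0.912), DMR6, which degrades salicylic acid (40.6 ± 17.7), JAZ1 (36.7 ± 16.6), the indole glucosinolate enzyme CYP79B2 (33.2 ± 35.3) and WRKY18 (13.2 ± 17.2). WRKY72 had no single region that met the rule. AT3G48640, AT5G60710, AT1G49000 and AT1G04360 were among the strongest of the others. The list genes lost were NRG1B (3.59 ± 2.45) and ZAR1 (2.00 ± 0.199), both among the weakest calls of their lists, and among the strongest other lost genes were AT1G18382 (94.1 ± 1.29), GRP2B and AT5G01734. The split across time and replicate gave 15 and 19 regions and that by replicate number 479 and 268. With equal numbers of peaks 31 regions were gained and 59 lost (34.4% gained against 86.0%), which cannot test the excess, since equal numbers push gains and losses towards balance. Losses then outnumbered gains, and the cause of that was not tested. Within pairs 1 and 2 alone 813 and 686 regions were gained and 216 and 213 lost.

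Regions gained in both genotypes, that is called in all 4 libraries at 2 h and none at 0 h, numbered 44. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave as many, the real one and that by replicate number with 159, so chance was not excluded. Counted by gene there were 42, of which 37 had such a region, among them PUB24, AT3G48640 (chromosome 3, 18021025 to 18021444, near a transcript end), BGLU27, AT1G14330, AT2G27389 and RALFL21, a signalling peptide gene. The reverse, called in all 4 libraries at 0 h and none at 2 h, held for 5 regions and, counted by gene, for 4, among them AT1G78840, AT1G12451 and AT3G18790. Of the 254 regions gained in WT, 83 were called in both mutant libraries at 2 h, 121 in 1 and 50 in none. At 0 h 13 of the 254 were called in both mutant libraries, 59 in 1 and 182 in none. Within replicate 1 alone 386 regions were called in both genotypes at 2 h and neither at 0 h, with 93 the other way, and within replicate 2 the numbers were 255 and 56. With equal numbers of peaks 5 regions were called at 2 h and not at 0 h, and 19 the reverse (20.8% against 89.8%), a setting that removes an excess whatever its source. The cause of the excess the other way was not tested.

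The genotype comparison asked which sites differed in calls between WT and the mutant, with the mutated genes given first. The serum was raised against all WRKY proteins, so another WRKY protein can keep a site called in the mutant. The counts therefore cannot show how many sites depend on WRKY18, WRKY40 and WRKY33. WRKY40 had peaks in all 8 libraries, the strongest on chromosome 1 at 30380370 to 30380725, at -3144 bp from its TSS, with percentiles of its strongest peak from 74.8 to 99.95. In replicate 1 of the mutant at 2 h that site lay inside a 4422 bp peak assigned to AT1G80831, the widest of all. WRKY18 had a peak upstream of its TSS in 4 of 8 libraries, 1 each in WT at 0 h and 2 h and both in the mutant at 2 h, with percentiles from 1.02 to 38.4. WRKY33 had a promoter peak in all 4 WT libraries, at -110 to -255 bp from its TSS, with percentiles from 82.9 to 94.2. In the mutant WRKY33 was called in replicate 2 at both times, at 578 and 568 bp from the TSS on the downstream side, with percentiles of 58.5 and 42.3, and in neither replicate 1 library. A peak at a gene's promoter does not check that the gene is mutated. FRK1, a receptor kinase gene used as a marker of flg22 responses, was called in both WT libraries at 2 h and in 1 library of each other group. That 1 library was replicate 2 each time, so the contrast rests on the replicate 1 call in WT at 2 h (percentile 12.68). In replicate 2 the percentiles were 23.6 and 32.35 in WT at 0 h and 2 h, and 45.73 and 68.3 in the mutant.

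At 2 h 62 regions were called in both WT libraries and neither mutant library, and 59 the reverse. Counted by gene the numbers were 52 and 55, of which 48 and 48 had such a region. List genes called in WT at 2 h and not in the mutant were ERF1B (32.3 ± 29.7, SD, n = 2), the salicylic acid receptor NPR3 (27.9 ± 37.7), CRK28 (12.4 ± 13.9) and WRKY1 (12.1 ± 5.15), and none of these 4 was called at 0 h in either genotype. ERF1B was called at different sites in the 2 libraries. AT3G61185 (70.7 ± 29.7), TBL15, IAGLU and AT5G64650 were among the strongest others. List genes called in the mutant at 2 h and not in WT were NPR1 (30.9 ± 40.7), the salicylic acid receptor and coactivator, RPM1 (27.2 ± 28.6) and MPK3 (18.5 ± 8.25), beside UBP20, OLEO4, LOX1, AT3G60850 and AT2G29065. The split across genotype and replicate gave 22 and 17 regions and that by replicate number 435 and 419. Within replicate pairs 1 and 2 alone, 436 and 520 regions were called in WT only and 488 and 672 in the mutant only.

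At 0 h 39 regions were called in both mutant libraries and neither WT library, and 19 the reverse. Counted by gene the numbers were 36 and 16, of which 33 and 16 had such a region. List genes called in the mutant alone were PEPR1 (36.7 ± 27.7, SD, n = 2), CRK2 (34.4 ± 1.17) and ZAR1 (2.00 ± 0.199), and the strongest others were AT2G39518, AT1G26380, AT2G33600, AT1G72300 and AT2G39210, the last at different sites in the 2 libraries. PEPR1, CRK2 and AT1G26380 were called in all 6 other libraries. No list gene was called in WT alone at 0 h, where the strongest genes were the calcium-dependent kinase CPK30 (67.5 ± 15.0, SD, n = 2), AT5G60710, RFO1, AT5G16110 and AT2G24693. The split across genotype and replicate gave 24 and 41 regions and that by replicate number 332 and 250. The larger genotype count, 39, was thus below the larger count of each other split. With equal numbers of peaks, which push the 2 directions towards balance, the counts were 23 and 24 (48.9% against 67.2%). Within replicate pairs 1 and 2 alone, 363 and 467 regions were called in the mutant only and 294 and 221 in WT only, and the WT replicate 1 list lacked 136 of its 1508 region numbers.

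Over both times 2 regions were called in all 4 mutant libraries and no WT library, at AT1G70770 (chromosome 1, 26693178 to 26693595, at -2109 bp from the TSS) and AT4G38810 (chromosome 4, 18119901 to 18120121, at -934 bp). No region was called in all 4 WT libraries and no mutant library. With peaks cut to 150 bp around their centre 1 such region appeared, the WRKY33 promoter region on chromosome 2 at 16107673 to 16108584, at -233 bp from the TSS, whose WT peaks otherwise merge with the downstream mutant peaks. This region was chosen after its values were seen. Few all-WT regions do not show that few sites depend on the mutated genes, since the serum was raised against all WRKY proteins.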

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

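One region moved in opposite directions after flg22 in the 2 genotypes, in all libraries of each: the promoter of CPC (AT2G46410, a root hair regulator; chromosome 2, 19050448 to 19050933, at -386 bp from the TSS) was called in both WT libraries at 0 h and neither at 2 h, and in neither mutant library at 0 h and both at 2 h. This difference was not tested, and 1 such region was seen, fewer than the 1.94 that independent lists would give, with 0 among genes. Its score percentiles lay between 3.10 and 16.4, among the weakest of each list.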

How the results depend on the processing

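W-box and tag-count alternatives were not run and have no value. With only peaks above each list's median score, regions gained after flg22 in WT numbered 126 and regions lost after flg22 in WT 45, mutant gains 57, regions at 2 h 37 in the mutant alone and 37 in WT alone, regions at 0 h 14 and 7, regions called in all 4 libraries at 2 h and none at 0 h 13, and all-mutant regions 1. With equal numbers of peaks, gains and losses were 105 and 125 in WT and 31 and 59 in the mutant, mutant-only regions 38 at 2 h and 23 at 0 h, and over both genotypes 5 at 2 h and 19 at 0 h, with 0 all-mutant regions. With the rule relaxed to 1 library of the other group at most, gains and losses were 576 and 246 in WT, and for regions gained after flg22 in wrky18/40/33 and regions lost after flg22 in wrky18/40/33 386 and 185; regions called at 2 h in wrky18/40/33 and not WT numbered 300 and regions called at 2 h in WT and not wrky18/40/33 323, while regions called at 0 h in wrky18/40/33 and not WT numbered 260 and regions called at 0 h in WT and not wrky18/40/33 154. With the replicate block (mean count per pair), the same 8 counts were 922 and 331.5, 749.5 and 214.5, 580 and 478, and 415 and 257.5, larger because each pair is read alone. Peaks of 150 bp gave 1 all-WT region. For peaks per library, 2 h minus 0 h, the difference was 439 at ef score 5 or more (exact permutation p = 0.143) and 580.8 under the replicate block (exact p = 0.125); for peaks per library, wrky18/40/33 minus WT, the replicate block gave 131.2 (exact p = 0.125). With WT 0 h replicate 1 at its highest region number, chosen after seeing the data, these were 546.8 (exact p = 0.0286, and 0.125 under the replicate block) and 97.25 (0.686 and 0.375). Paired and leave-one-out tests of assigned genes, promoter share and intergenic share were also added after seeing the data.

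Leaving out 1 library loosens the rule, and counts rose: gains to 402 to 804 and losses to 129 to 246 in WT, 241 to 668 and 66 to 150 in the mutant, mutant-only and WT-only regions to 174 to 540 and 157 to 332 at 2 h and 126 to 339 and 71 to 170 at 0 h, over both genotypes 51 to 106 at 2 h and 6 to 22 at 0 h, and 3 to 10 all-mutant and 0 to 6 all-WT regions. The difference in peaks between times was 537.1 to 653.7 (exact permutation p = 0.0571) and between genotypes 12.7 to 268. Of the 48 tests of bound lists (each list in each group) 28 to 30 passed. Of the tests of gained or lost genes 0 to 2 passed, in each case the immune receptors. Without WT 0 h replicate 1 the call in the mutant changed only through the adjustment. With all protein-coding genes as background 3 such tests passed (ethylene genes gained in WT, immune receptors lost in both genotypes). Of the 28 bound-list tests that passed at first, 21 passed above the median score, 24 with the 2000 bp window, 20 with the 1000 bp window and 28 with all nuclear genes. The odds ratio fell to 0 for VQ genes in the mutant at 0 h (median score) and for ethylene genes in WT at 0 h (1000 bp). Of 86 named gene differences 56 held with equal numbers, 26 above the median score and 67 with the 2000 bp window, and none reversed. The cause of shifts not given here was not tested.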

Other observations

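Chosen after seeing the data were the tests of the gene families, of the splits of the time contrast, of equal list lengths as an explanation (the setting itself was fixed beforehand), of region width by replicate, of the absent rows and of the intergenic share. Among 17 families picked by gene symbol, U-box ubiquitin ligases stood out: 7 of 23 were bound in WT at 2 h (30.4% against 3.85% of other genes; Fisher's exact adjusted p = 0.000620 over 68 tests) and 7 of 23 in the mutant at 2 h (same adjusted p), against 3 and 4 at 0 h (adjusted p = 0.198 and 0.0607). PUB23 was called in all 8 libraries, PUB24 in all 4 at 2 h and none at 0 h, and PUB22, PUB12 and PUB26 in all 4 at 2 h and in some at 0 h. PUB12, PUB22, PUB23 and PUB24 also belong to the fixed list of pattern perception genes, which had already passed. The family result is therefore not independent of that list. Receptor-like proteins were bound at 8 of 55 in the mutant at 0 h and 9 of 55 at 2 h (Fisher's exact adjusted p = 0.00522 and 0.00509), and at 6 of 55 in WT at each time (adjusted p = 0.0607 and 0.187); RLP2 and RLP4 were called in all 8 libraries. Differences between groups were not tested for either family. NAC, MYB, CYP and ribosomal protein families did not pass in any group.

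A hypothesis was that WRKY genes carry several separate sites each. The 33 WRKY genes with a region had 1.42 ± 0.708 regions (SD) against 1.099 ± 0.340 for 3492 other genes, and 30.3% against 8.79% had more than 1 (permutation test on the means, two-sided, p = 0.00022). WRKY11, WRKY17, WRKY28 and WRKY72 had 3 regions each. The count includes regions called in 1 library only, so calls that shift between libraries also add regions. WRKY72, with 3 regions, had none that met the rule for a gain in either genotype. The number of libraries calling a gene was not taken into account, and nearest-promoter assignment could also give isolated genes more regions. Clustered sites at WRKY genes are thus 1 possible reading, which this test cannot separate from the others.

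For the 44 regions called in all 4 libraries at 2 h and none at 0 h, 2 of the 35 splits of the 8 libraries gave as many. These were the real one and the split by replicate number (159 regions), which follows the shared replicates, so chance was not excluded at a share of 0.05. The highest of the remaining 33 splits gave 14. Of the 18 splits with 2 libraries of each number per side the next highest gave 7, but 18 splits cannot give a share below 0.05. Longer 2 h lists may account for the excess over losses. With lists of equal length 5 regions were called at 2 h and not at 0 h, against 19 the other way. Equal length removes an excess whatever its source, so these counts do not decide it. They went past balance to an excess of losses, and the cause of that was not tested. The median score percentile of the 44 regions was 45.2 (bootstrap 95% interval 38.7 to 52.1). An interval wholly above 30 had been meant to exclude longer lists as the explanation. Equal length leaves out the lowest 31.1% to 38.0% of the 2 h lists, so that bound decides nothing. More occupied sites after flg22 would lengthen the lists too, and the 2 cannot be told apart from peak lists. For genotype, 22 of the 35 splits gave at least 2 regions (highest other 159, by replicate number), so chance was not excluded.

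A further 250 regions followed the replicate number, 91 called only in the 4 replicate 1 libraries and 159 only in the 4 replicate 2 libraries. They included NPR4 and WOX14 (replicate 1) and WRKY7 (replicate 2). The 250 regions had a median percentile of 51.1 (bootstrap 95% interval 46.3 to 53.8), wholly above the preset bound of 30. This cannot exclude calls near the score threshold. Calls in all 4 libraries of a number already select stronger calls, and the value does not show how near the threshold a region lay in the lists lacking it. Region widths parted by number, with the narrowest replicate 1 median 140 bp above the widest of replicate 2, which is consistent with a batch in fragment length or library preparation. A biological difference between the replicates stays open and was not tested.

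Regions called everywhere except WT 0 h replicate 1 numbered 59, led by RLP32 (mean percentile 99.7 in the other lists, chromosome 3, 1648464 to 1648878), AT5G47225 and AT3G26910, with CNI1 and GBF1 also among the highest. Their median percentile was 59.8 (bootstrap 95% interval 51.9 to 69.6), wholly above the preset bound of 30. This cannot test for calls near the score threshold, since a call in every other list already selects stronger calls. Medians for regions absent from any other single library were lower, at 40.5 to 55.4, but also above 30. Of the 59 regions 11 lay above percentile 80, and none did for any other library. Rows absent from that table, 136 in number, are a candidate explanation. If all of them had lain in regions gained after flg22 in WT, 118 of the 254 would remain. No biological explanation was tested.

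Whether gained regions lie farther from promoters was left open: 12 of 44 (27.3%) were intergenic against 16.7% of the regions called in all 8 libraries (Fisher's exact test, two-sided, p = 0.0964). In the larger sets that contain these 44, which were not tested, 22.8% of the 254 WT gains were intergenic and 54.7% lay at promoters, and 21.6% and 63.1% of the 111 mutant gains, against 64.7% at promoters for the regions called in all 8 libraries.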
